A study of Mus musculus with 28 samples.

How the data were processed

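The series measured RNA from skin hair follicle stem cells of wild-type (WT) mice and of mice with a conditional knockout (cKO) of Alkbh5, an enzyme that removes the methyl mark m6A from RNA. Mice were at postnatal day 69. Of 28 samples, 12 RNA-seq libraries were analysed here, with 2 mice per genotype in each of 3 datasets: bulge stem cells and hair germ stem cells by SHERRY2, and hair germ stem cells by SMART-seq. The 16 m6A libraries (immunoprecipitate and input) were not analysed here. Per the labels, cells came from a flow cytometer and their RNA was prepared with TRIzol. SHERRY2 tags RNA/cDNA hybrids directly with a transposase, and SMART-seq amplifies full-length cDNA. Sorting markers, the Cre driver and the deleted exon are not given in the sources used here.

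For the bulge, the deposited table gives a read count per gene and an FPKM value per gene for each library, with Ensembl IDs, positions and exonic sizes. The FPKM of the authors followed from their counts, the exonic size and the summed count of the library, with a largest relative difference of 0.492% over genes with at least 100 reads and an FPKM of 1 or more. For hair germ SHERRY2, the deposited table is laid out as a DESeq2 result, with a normalized signal (read counts divided by a size factor) per library, a log2 fold change with its standard error, a Wald score, and unadjusted and adjusted p-values. It lists 47243 genes with a read in 1 or more libraries. The sign of the deposited score was opposite to that of the log2 fold change for all of these genes, so directions were taken from the library values. For hair germ SMART-seq, the deposited table gives read counts per versioned Ensembl ID. Per the submitters' processing notes, FastQC, Trim Galore, STAR, featureCounts and DESeq2 were used with GRCm38 and mm10 for the SHERRY2 batch. For the SMART-seq batch, the notes also name fastp, HISAT2, SAMtools, deepTools and Subread, and the build GRCm39. Versions, the annotation, and whether strand was used in counting are not given in the sources used here.

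Of 56691 IDs in the bulge table, 52073 matched the gene name reference and 2639 stayed without a symbol. Of 57010 in the SMART-seq table, 52029 matched and 1606 stayed without one. The hair germ SHERRY2 table gives symbols only. The bulge table names no build. Only 3.13% of 38989 genes with a shared symbol started within 1000 bp of their start in the RefSeq annotation of GRCm38.p6, so positions are given as that table gives them. No genome sequence was used, so GC content was not checked. Columns of the hair germ SHERRY2 table were assigned to genotypes by their names, and their mouse numbers were taken from the same names.

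Bulge and SMART-seq counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after TMM scaling and filterByExpr, comparing cKO with WT without other terms. Tests were two-sided, and adjusted p-values followed Benjamini-Hochberg at 0.05. The design had foreseen counts for hair germ SHERRY2. Because the values are normalized, the test written for that case was used: limma 3.58.1 with an intensity trend on log2(normalized count + 1), for genes with a mean of at least 1. Its fold changes are on that scale and understate changes of low genes. In each of those columns, 100% of values were whole multiples of 1 step within 0.01 reads, so whole reads were recovered (size factors 0.632 to 1.36). edgeR on these reads was added after seeing the data, for the genes that pass filterByExpr. DESeq2 1.42.0 on them gave the deposited log2 fold changes with a correlation of 1 across genes and a largest p difference of 1.4e-05.

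Before the data were examined, 35 gene lists were fixed. They were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists with at least 5 tested members. Camera with an estimated correlation and fry were run beside it. With 2 against 2 libraries, the estimated correlation reached 0.945 in the bulge and 0.98 in SMART-seq (both G2 and M phase). It reached 0.983 in hair germ SHERRY2 (ribosomal protein genes). No list kept its call in any dataset with an estimated correlation. That form of camera rests on the few residual degrees of freedom of these fits, so hardly any list could pass, whatever its correlation. The bulge p53 list, with an estimate of -0.0592, went from an unadjusted p of 6.85e-06 to 0.041 in camera. Such values leave a list undecided. Counts of list members past 0.05 are given over all genes and adjusted over the list alone. A list's median was also placed among 10000 random lists matched in 20 bins of expression and 5 of exonic length. Gene Ontology terms and pathway terms of the bulge table with 10 to 300 genes were tested by camera as an addition made after seeing the data. Differences of the genotype effect between datasets were tested in joint edgeR fits with a dataset-by-genotype term, also chosen after the data were seen. These fits take 1 spread per gene for both datasets, although the tables differ in unit, annotation and depth. Their p-values may therefore be too low where hair germ libraries vary more. The foreseen fits of hair germ against bulge, and of both hair germ protocols together, were not made because of these differences, which limit the joint fits as well.

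Genes named in the text follow a rule fixed beforehand. It takes Alkbh5, then the 10 largest and 10 smallest log2 fold changes per comparison among genes past 0.05 with non-overlapping groups and at least 5 CPM in the higher group, without predicted genes, clones, pseudogenes and receptor families. Where fewer than 5 passed in a direction, places up to 5 went to the genes of lowest p, said not to have passed. Of each list discussed, up to 4 members of lowest p are named. Other genes named were chosen after their values were seen, and this is said beside them. Some genes that these rules select are not reported here. For the technical explanations by handling stress, genomic DNA and time of day, the requirement for a verdict was raised after the values were seen, which left all 3 open.

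The main tests of single genes were tried on simulated data drawn from the library means and sizes, with 100 genes changed 2-fold and 100 changed 4-fold. Genes were drawn independently, so the false calls do not cover shifts that many genes share within a mouse. The fry test, the random lists and the joint fits were not simulated. edgeR recovered 58 and 96 of these in the bulge with 6 false calls, and 5 and 61 in SMART-seq with 3. For hair germ SHERRY2, limma recovered 0 of each, and edgeR on recovered reads 0 and 8. Simulated reads there followed library totals, but for limma they were scaled by the real size factors, which do not follow those totals. In cKO these were 1.36 for 1526070 reads and 1.22 for 2317407. Every simulated gene thus differed between libraries of 1 group, so the 0 of limma does not measure its power. Intervals on counts are 95% and cover counting error only, because reads without molecular identifiers are not independent molecules. A two-sided exact permutation test of 2 against 2 cannot go below p = 0.33, so none was used. Alternatives were other size factors, DESeq2, no low-count filter, another pseudocount (0.1), a log2 fold change over 1, the mouse number as a term, and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.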

Results

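RNA of sorted hair follicle stem cells from Alkbh5 cKO and WT mice was compared at postnatal day 69, an age the series places around the change of the follicle from rest (telogen) to growth (anagen). Bulge stem cells are the long-lived reserve of the follicle, and hair germ stem cells lie beneath them and are the first to divide when growth starts. Each dataset had 2 WT and 2 cKO mice. Bulge libraries held 14676168 to 21187283 reads in genes, with 21171 to 22959 genes detected. Hair germ SMART-seq libraries held 9001396 to 14416601 reads, with 22992 to 24641 genes detected and 12.5 to 15.2% of reads in mitochondrial genes. Hair germ SHERRY2 libraries were shallower: 1513001 and 488648 reads for the WT mice, and 1526070 and 2317407 for the cKO mice. They nonetheless had reads on 38272 to 42826 of 47243 listed genes. Olfactory and vomeronasal receptor genes, which skin stem cells have no known use for, had reads in 1609 to 1788 of 1907 cases there, against 44 to 54 of 2002 in the bulge and 37 to 65 of 2005 by SMART-seq. Genes whose symbol was listed in the bulge under an ID with 0 reads in all 4 libraries took 3.44 and 9.08% of the reads of the hair germ SHERRY2 WT libraries and 5.19 and 2.44% of those of the cKO libraries, against 0.155 to 0.201% by SMART-seq. In the bulge, other IDs of these symbols held 0.0225 to 0.0291% of the reads. By Xist and Y-linked genes, WT mouse 2 of the bulge and cKO mouse 1 of hair germ SHERRY2 were male and the other mice of these datasets female. In SMART-seq, number 1 of each genotype was female and number 2 male.

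**Figure D1:**
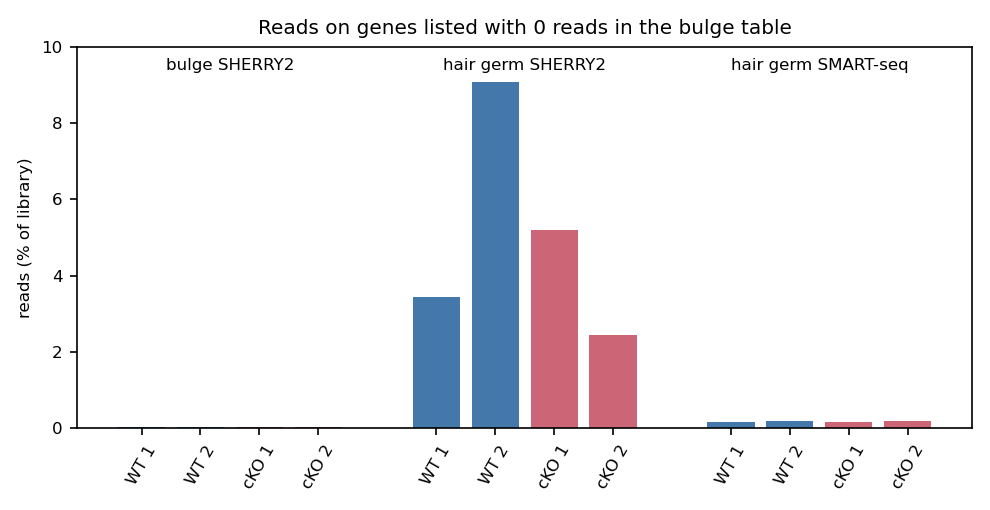
Reads on genes whose symbol was listed in the bulge table under an ID with 0 reads, as % of each library, for WT (blue) and cKO (red) libraries. The hair germ SHERRY2 libraries lie between 2.44 and 9.08% and the SMART-seq libraries at 0.201% or less, while the bulge lies near 0 by the choice of genes.

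Alkbh5 itself (ENSMUSG00000042650, chromosome 11, 60427207 to 60449338 in the bulge table) was nearly lost in the bulge cKO libraries. Its level was 101.2 ± 8.88 CPM in WT and 3.278 ± 1.2 in cKO (mean ± SD, n = 2 each), which is 3.24% of WT and 30.9-fold lower. The 4 libraries had 2095 and 1351 reads in WT and 68 and 50 in cKO. In hair germ SHERRY2 it was 56.92 ± 26 CPM in WT and 13.1 ± 4.33 in cKO (n = 2 each), or 23% of WT, from 95 and 30 reads against 27 and 16. In hair germ SMART-seq it was 115 ± 29.6 CPM in WT and 94.24 ± 15.1 in the libraries labelled cKO (n = 2 each), or 81.9% of WT, and the groups overlapped. The log2 fold changes were -4.97 in the bulge (SE 0.28, adjusted p = 0.000492, edgeR with Benjamini-Hochberg), -1.98 in hair germ SHERRY2 (SE 0.61, adjusted p = 0.724, limma) and -0.28 in SMART-seq (SE 0.26, adjusted p = 1, edgeR). With edgeR on recovered reads, the hair germ SHERRY2 value was -2.31 (adjusted p = 0.00993), a call kept without WT mouse 2 and lost when any other library was left out. Every direction given for SMART-seq below therefore rests on labels that the Alkbh5 level of these libraries did not bear out.

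**Figure D2:**
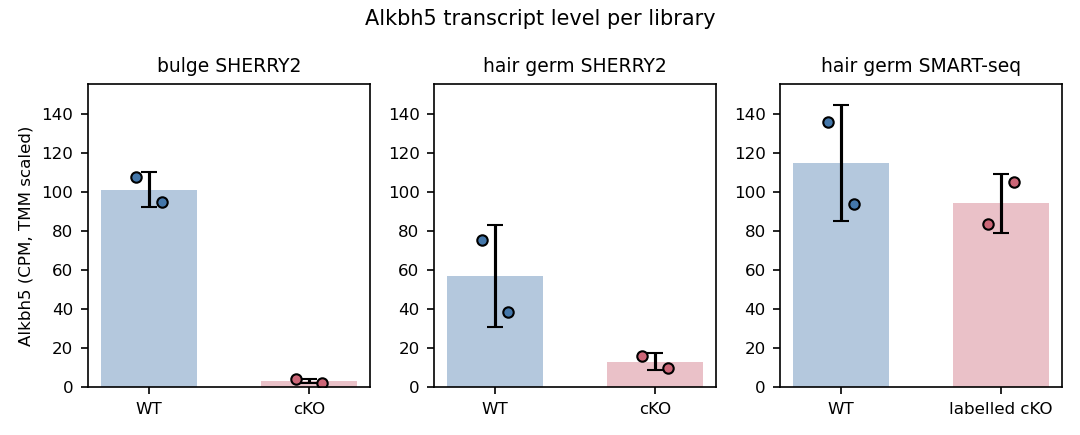
Alkbh5 level in CPM per library (points), with the mean (bars) and SD (error bars) of 2 mice per group, for the 3 datasets. The level in cKO is 3.24% of WT in the bulge, 23% in hair germ SHERRY2 and 81.9% in the SMART-seq libraries labelled cKO.

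In bulge stem cells, loss of Alkbh5 went with higher levels of cell cycle genes and of p53 target genes, and with lower levels of immediate early genes and ribosomal protein genes. Antigen presentation genes, which mark immune cells other than the sorted ones, were lower in these libraries too. Of 15672 genes tested, 476 passed an adjusted p of 0.05 in edgeR, 225 higher and 251 lower in cKO, and 2968 had an unadjusted p under 0.05. The count was 464 without WT mouse 1, 1601 without cKO mouse 1, 218 (72 higher) without WT mouse 2 and 733 without cKO mouse 2, and all 476 genes kept their sign in each of these fits. The kept signs were nearly given in advance, because all 476 genes had non-overlapping groups. DESeq2, run on 26954 genes without the filterByExpr step, called 1187 genes.

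Targets of p53, the transcription factor that halts division after DNA damage, rose as a list, and of the 10 lists past the threshold in camera this one also passed in fry. This list, called p53 targets throughout, was fixed to hold other cell cycle inhibitors as well, among them Cdkn1c. Of 14 measured members, 6 rose and 0 fell over all genes tested, and 8 rose and 2 fell adjusted over the list alone. The list had a median log2 fold change of 0.71 (adjusted p = 3.88e-05, camera; adjusted p = 0.905 with an estimated correlation; adjusted p = 0.0147, fry). Outside the lists that passed in camera, hair matrix and shaft genes passed in fry too (adjusted p = 0.00876). They had 6 of 11 members positive, a median of 0.115 and 0 past the threshold over all genes. A pass in fry alone therefore does not show that a list moved as a whole. Zmat3, an RNA-binding p53 target, rose from 39.7 ± 3.01 to 156 ± 8.05 CPM (mean ± SD, n = 2 each; log2 1.97, SE 0.15, adjusted p = 0.00177, edgeR). Eda2r, a death-domain receptor, rose from 9.98 to 36.7 CPM (adjusted p = 0.00404, edgeR), Ccng1 from 98.2 to 318 (adjusted p = 0.00448) and Sesn2 from 30.6 to 110 (adjusted p = 0.00483). Cdkn1a, the inhibitor that carries out p53 arrest, rose by 1.05 (adjusted p = 0.0249, edgeR) and Mdm2, which degrades p53, by 0.77 (adjusted p = 0.0345). These last genes were named after their values were seen. Leaving out each library in turn gave list medians of 0.56 to 0.86, with the list past the threshold each time in camera. No matched random list of 10000 had so high a median.

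Cell cycle genes rose as groups at the same time. All 22 S phase genes had positive values, with a median of 1.09 (adjusted p = 1.13e-12, camera; adjusted p = 0.905 with an estimated correlation). Of these, 4 passed over all genes and 18 adjusted over the list alone, among them the nucleotide reductase subunits Rrm1 (log2 1.40, adjusted p = 0.0254, edgeR) and Rrm2 (1.65, adjusted p = 0.03), Ccne1 (1.91, adjusted p = 0.0351) and Chaf1b (1.13, adjusted p = 0.0494). All 24 G2 and M phase genes were positive as well, with a median of 1.01 (adjusted p = 8.34e-12, camera; adjusted p = 0.905 with an estimated correlation). Here 2 passed over all genes and 19 adjusted over the list alone. Mki67, a marker of dividing cells, went from 130 ± 21.9 to 320 ± 120 CPM (adjusted p = 0.0465, edgeR) and Top2a from 132 ± 9.63 to 305 ± 113 (adjusted p = 0.0472). Bub1 (log2 1.48) and Kif23 (1.23) did not pass. The size of this change differed between mice: without cKO mouse 2 the G2 and M phase median was 0.40, and without cKO mouse 1 it was 1.45. Without the male WT mouse 2 no member of either list passed over all genes. The lists still passed in camera there (S phase 0.78, adjusted p = 8.13e-11; G2 and M phase 0.88, adjusted p = 2.11e-10). Among Gene Ontology and pathway terms, DNA replication (adjusted p = 1.24e-06, camera), homologous recombination (adjusted p = 9.54e-06) and the Fanconi anemia pathway (adjusted p = 1.15e-05), which repairs DNA cross-links, were higher, each with an adjusted p of 0.999 with an estimated correlation.

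Immediate early genes, which respond within minutes to growth signals and also to cell dissociation, were lower. All 22 members were negative, with a median of -2.01 (adjusted p = 3.02e-17, camera; adjusted p = 0.905 with an estimated correlation), 8 passed over all genes and 21 adjusted over the list alone. Egr3 went from 164 ± 0.868 to 39.8 ± 10.2 CPM (log2 -2.05, SE 0.20, adjusted p = 0.00374, edgeR), and Egr2 changed by -2.72 (adjusted p = 0.0085), Ier3 by -1.18 (adjusted p = 0.0254) and Hspb1, a heat shock gene, by -1.53 (adjusted p = 0.027). The list median was -3.07 without cKO mouse 1, and with all libraries the members ran highest in WT mouse 1 and lowest in cKO mouse 2. NF-kB and cytokine genes fell as a group in camera (13 of 15 negative, median -0.79, adjusted p = 0.00674; adjusted p = 0.905 with an estimated correlation; -0.49 without cKO mouse 1). The inhibitors Nfkbia (-1.59, adjusted p = 0.0425, edgeR) and Tnfaip3 (-1.68, adjusted p = 0.0454) fell, while Ccl20 (1.41) and Il6 (-3.39) did not pass. Immune cell genes, which mark cells other than the sorted ones, had 16 of 17 members negative with a median of -1.71 (adjusted p = 1.99e-09, camera; adjusted p = 0.905 with an estimated correlation), 5 past the threshold over all genes and 12 adjusted over the list alone. The antigen presentation genes Cd74 (110 ± 22.4 to 33.3 ± 10.7 CPM, adjusted p = 0.0165, edgeR), H2-Aa (log2 -1.86, adjusted p = 0.0231) and H2-Ab1 (-1.90, adjusted p = 0.0361) and the dendritic cell gene Cd83 (-1.89, adjusted p = 0.0465) were among them. All 28 ribosomal protein genes were negative with a median of -0.68 (adjusted p = 1.31e-14, camera; adjusted p = 0.905 with an estimated correlation), 2 passed over all genes, among them Rpl37 (-0.88, adjusted p = 0.0448, edgeR), and 25 adjusted over the list alone. Random lists of like expression and length had medians of -0.67 to -0.18. They could hold other ribosomal protein genes, so they cannot show whether other abundant short genes shared the shift. The 193 genes of the cytoplasmic translation term had a median of -0.68 too.

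Single genes with the largest rises included signalling and matrix genes that were low or near silent in WT. Serpine2, a secreted protease inhibitor, rose from 1.11 ± 0.163 to 73.2 ± 6.1 CPM (log2 6.02, SE 0.23, adjusted p = 0.000121, edgeR). Mcam, a cell adhesion molecule, rose from 7.82 ± 3.62 to 396 ± 67.2 CPM (adjusted p = 0.000492), and Ddit4l, an mTOR inhibitor, from 1.02 ± 0.941 to 39.3 ± 3 (adjusted p = 0.00296). The glutamate receptor gene Gria3 had 2 reads in WT and 1448 in cKO, a ratio of 740 with a counting interval of 205 to 6118. Celf5 (log2 5.19), Susd4 (4.83), the cartilage collagen Col2a1 (4.59), the guidance factor Slit1 (4.55), the collagen hydroxylase Plod2 (4.45) and Pde7b (4.37) rose too, with adjusted p from 0.00067 (Plod2) to 0.0465 (Pde7b) in edgeR. After Alkbh5, the largest falls among the named genes were in Arc, from 549 ± 74 to 19 ± 18 CPM (log2 -4.87, SE 0.66, adjusted p = 0.0128, edgeR), and the nuclear receptor Nr4a3 (-4.77, adjusted p = 0.00549), both induced by stimulation. The vasoactive peptides Edn2 (-4.22) and Adm (-3.85), the stress gene Gadd45g (-3.31), the lipoxygenase Alox12e (-3.30) and the chemokine receptor Ccrl2 (-2.95) fell with adjusted p from 0.00448 (Edn2) to 0.0255 (Ccrl2) in edgeR. Igfbp3, which binds insulin-like growth factors, fell from 744 ± 69.9 to 88.5 ± 32.7 CPM (adjusted p = 0.0028, edgeR). Without WT mouse 1, Ccrl2 lost its call (adjusted p = 0.0752, edgeR), and without WT mouse 2 so did Pde7b (adjusted p = 0.0565), which did not pass in DESeq2 with all libraries either (adjusted p = 0.112). Mcam, Celf5, Plod2, Adm and Pde7b overlap genes on the opposite strand, and Gria3 and Pde7b genes on the same strand, so their reads cannot be assigned with certainty.

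Pathways that govern the start of growth had single genes that changed, while the lists did not pass with all libraries. In the Wnt list, which drives anagen, Wnt7a rose from 1.08 ± 0.214 to 13.3 ± 0.385 CPM (adjusted p = 0.00383, edgeR) and Ccnd1 from 141 to 370 (adjusted p = 0.0152), while Myc fell from 218 to 83.3 (adjusted p = 0.0323). Wnt3 (log2 0.60) did not pass. Of 22 genes, 4 rose and 3 fell adjusted over the list alone (list adjusted p = 0.511, camera). In the BMP list, which holds stem cells at rest, Id1 (-1.59, adjusted p = 0.00836, edgeR), Bmp2 (-1.35, adjusted p = 0.0116) and Id3 (-1.07, adjusted p = 0.0434) fell, and Bambi (-1.13) did not. The list did not pass (adjusted p = 0.265, camera). Without cKO mouse 1 the BMP list passed as lower with 5 members past the threshold (median -0.18, adjusted p = 0.0432, camera), and so did TGF-beta targets (-0.47, adjusted p = 0.0432; -0.25, adjusted p = 0.366 with all libraries). Bulge stem cell genes did not pass as a list with all libraries (0 of 25 passed, median -0.13, adjusted p = 0.186, camera). Their lowest p belonged to Foxc1 (-0.84), Krt15 (-0.77), Fgf18 (1.31) and Cd200 (-0.91). This rested on which cKO mouse was kept: without cKO mouse 1 the list was lower, with 10 of 25 members past the threshold (-0.54, adjusted p = 6.95e-07, camera), and without cKO mouse 2 its median was 0.11 (adjusted p = 0.237). It was also lower without WT mouse 2 (-0.19, adjusted p = 0.0269). Hair germ genes had 0 of 14 past the threshold and 3 lower adjusted over the list alone, Runx1 (-0.69), Cxcl14 (-1.18) and Lef1 (-1.80), with Bmpr1a at 0.38. Among m6A enzymes and readers, 1 of 20 passed, Alkbh5, and Ythdc2 (0.56), Hnrnpc (-0.33) and Wtap (-0.28) came next without passing (list adjusted p = 0.744, camera). Of 18 sebaceous and upper follicle genes, the lipid enzymes Elovl6 (1.60, adjusted p = 0.00907, edgeR), Elovl3 (2.63, adjusted p = 0.02), Scd1 (1.18, adjusted p = 0.0288) and Far2 (1.24, adjusted p = 0.0438) rose and 1 fell (list adjusted p = 0.285, camera). Cholesterol synthesis rose in camera (15 of 19 positive, median 0.45, adjusted p = 0.000638; adjusted p = 0.92 with an estimated correlation), with 1 member past the threshold over all genes and Lss (0.64), Dhcr7 (0.80) and Idi1 (0.53) not past it. It did not pass without the male WT mouse 2 (median 0.22, adjusted p = 0.105, camera), and the median was 0.29 without cKO mouse 2. Epidermal differentiation fell (19 of 22 negative, median -0.43, adjusted p = 0.00925, camera; adjusted p = 0.92 with an estimated correlation), with Sprr1a (-1.92, adjusted p = 0.0386, edgeR) and Krtdap (-0.76, adjusted p = 0.0425) passing and Klk7 (-1.55) and Ivl (-1.19) not. That call was lost without WT mouse 1 (median -0.17, adjusted p = 0.154) and without cKO mouse 2 (-0.24, adjusted p = 0.279), while the median was -0.93 without cKO mouse 1 and -0.80 without WT mouse 2. Nuclear genes of oxidative phosphorylation were slightly lower (median -0.15, adjusted p = 0.0457, camera; adjusted p = 0.92 with an estimated correlation). Random lists of like expression and length had medians of -0.43 to -0.06, so this list was not lower than such genes. Its median shrank to -0.02 without cKO mouse 1 and to -0.07 without WT mouse 2.

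**Figure D3:**
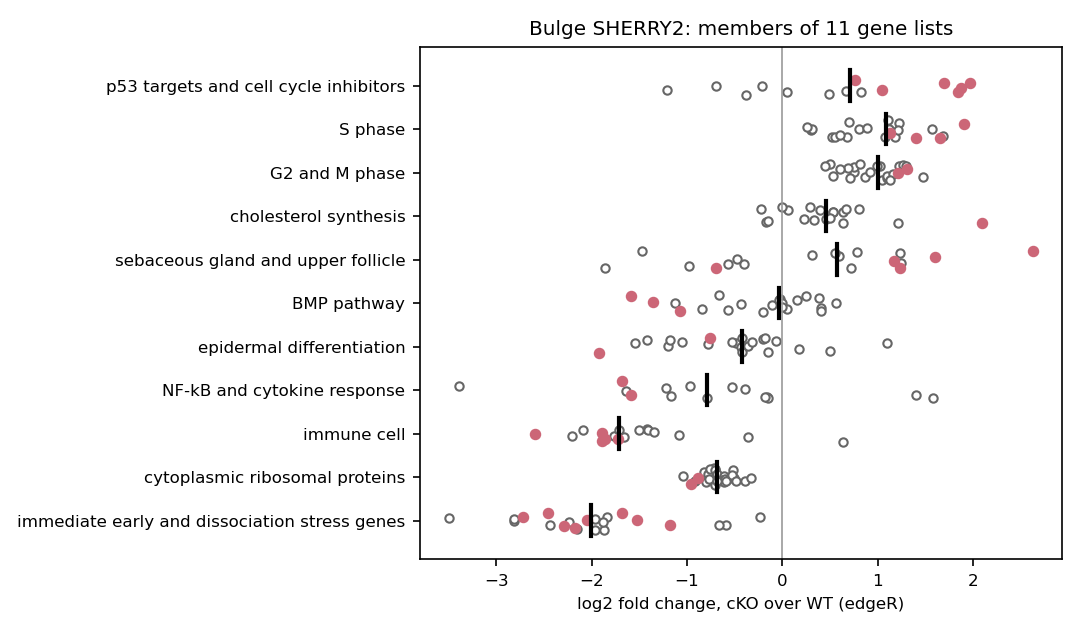
Log2 fold change (cKO over WT, edgeR) of each measured member of 11 gene lists in bulge stem cells, with members past an adjusted p of 0.05 filled and list medians as vertical bars. Medians run from -2.01 (immediate early genes) to 1.09 (S phase).

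In hair germ stem cells measured by SHERRY2, 3 genes were higher in cKO, among them a hair keratin-associated gene and a hormone subunit gene, and these calls depended on the setting. Of 38953 genes tested, limma called 3 higher and 0 lower, with 1801 at an unadjusted p under 0.05. DESeq2 called 0, limma with a pseudocount of 0.1 or without a filter on the mean called 0, and edgeR on recovered reads called 17 higher and 46 lower of 16707. The limma calls also changed with the library left out. limma recovered 0 of 100 simulated 4-fold changes, but in that simulation every gene was offset between libraries of 1 group. Its power on these libraries is therefore not known from that value. Gpha2, a hormone subunit gene, rose from 9.9 ± 9.53 to 89.6 ± 18.8 normalized counts (mean ± SD, n = 2 each; log2 3.39, SE 0.61, adjusted p = 0.00887, limma; adjusted p = 0.000999, edgeR on recovered reads), though it overlaps Ppp2r5b on the opposite strand. The hair keratin-associated gene Krtap17-1 rose from 1 read in WT to 61 in cKO, a ratio of 31.8 with a counting interval of 5.49 to 1275 (adjusted p = 0.0179, limma). Gpha2 lost its call in limma and in edgeR on recovered reads whichever library was left out, and Krtap17-1 in limma without cKO mouse 1 or WT mouse 1. The other was the predicted gene Gm15706, with 0 reads in WT and 25 and 16 in cKO, named because the count was small. Etv4, a transcription factor downstream of FGF, did not pass in limma (log2 3.17, adjusted p = 0.059) and did in edgeR on recovered reads (3.14, adjusted p = 0.000664), a call lost there whichever library was left out. Snhg9 (1 against 39 reads, ratio 20.3, interval 3.44 to 823) and Hoxc13, a hair shaft regulator (log2 2.88, adjusted p = 0.116, limma), did not pass. Lower values that did not pass in limma were those of barrier genes of differentiated epidermis, Lce1i (35 against 1 reads, ratio 0.0149, interval 0.000366 to 0.0885), Kprp (-2.92, adjusted p = 0.152; -4.11, adjusted p = 3.55e-07, edgeR on recovered reads, from 272 and 11 reads in WT against 7 and 16 in cKO), Lce1d (-2.62) and Cldn23 (47 against 3 reads, ratio 0.0332, interval 0.00662 to 0.103), and of Acp7 (-2.59; adjusted p = 0.0153 in edgeR on recovered reads), which like Snhg9 overlaps a gene on the opposite strand. The calls of Kprp and Acp7 on recovered reads were kept without WT mouse 2 only. WT mouse 1 held 32 of the 35 WT reads of Lce1i, 56 of the 59 of Lce1d and 45 of the 47 of Cldn23, so these values rest on that mouse. In the same way, cKO mouse 1 held 181 of the 194 cKO reads of Hoxc13 and 53 of the 61 of Krtap17-1. The authors' own table had 0 genes by adjusted p (smallest 0.243), and 289 higher and 89 lower by unadjusted p.

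The scale of these libraries matters for gene lists. Over the 16707 genes that pass the edgeR filter, the median log2 fold change was 0.25 in normalized counts and -0.03 after TMM scaling, so abundant genes as a whole lay higher in cKO in the first. Lists are therefore set beside random lists of like expression and length. Hair germ genes had a median of 0.77, with 14 of 15 positive (adjusted p = 1.48e-05, camera; adjusted p = 0.921 with an estimated correlation), against -0.03 to 0.63 for random lists. Of them 0 passed over all genes and 3 rose adjusted over the list alone: Hoxc13, Msx2 (log2 1.77) and Pdgfa (2.48), followed by Gli1 (1.14). The rise of Hoxc13 rested mainly on cKO mouse 1. Wnt genes had a median of 0.66, with 21 of 26 positive (adjusted p = 0.0148, camera; adjusted p = 0.921 with an estimated correlation), against 0.08 to 0.60, led by Ccnd1 (2.58), Nkd1 (1.57), Tcf7 (1.53) and Wnt7a (1.24). S phase genes had a median of 1.04 with 20 of 21 positive (adjusted p = 5.13e-06, camera; adjusted p = 0.921 with an estimated correlation) against 0.27 to 0.79, led by Mcm7 (2.01), Dut (1.58), Cdt1 (1.46) and Gins2 (1.36), while G2 and M phase genes did not pass (median -0.06, adjusted p = 0.673; 0.67 without cKO mouse 1 and -0.86 without cKO mouse 2). The G2 and M phase median lay below its random lists (0.29 to 0.74). So did that of immediate early genes, which did not pass either (-0.22 against 0.54 to 1.03, adjusted p = 0.592, camera). Nuclear genes of oxidative phosphorylation were all 22 positive (median 1.23, adjusted p = 1.6e-07, camera; adjusted p = 0.921 with an estimated correlation) against 0.61 to 1.10, among them Ndufa1 (1.82), Ndufa2 (1.89), Cox5a (1.58) and Cox7a2 (1.42). Glycolysis genes passed as well (median 0.84 against 0.23 to 0.77, adjusted p = 0.00216, camera; adjusted p = 0.921 with an estimated correlation). Wnt, S phase, oxidative phosphorylation and glycolysis genes were lowest in WT mouse 2 and highest in cKO mouse 2. These libraries had the largest (9.08%) and smallest (2.44%) share of reads on genes with an ID at 0 reads in the bulge. Oxidative phosphorylation genes had deviations of -1.38 and 1.44 there, while WT mouse 1 (0.143) lay above cKO mouse 1 (-0.0281).

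Bulge stem cell genes (median 0.59, adjusted p = 0.0049, camera), cholesterol synthesis (0.60, adjusted p = 0.00104), p53 targets (0.60, adjusted p = 0.0108) and Hedgehog genes (0.57, adjusted p = 0.0128) also passed, each with an adjusted p of 0.921 with an estimated correlation. They lay at percentiles 81.7, 89.6, 72.1 and 97 of their random lists, inside the central 95% of genes of like abundance. In the p53 list, Bax (log2 2.22) and Ccng1 (2.26) passed adjusted over the list alone, and Phlda3 (1.74) and the cell cycle inhibitor Cdkn1c (1.24) did not. Of cholesterol genes, Mvd (2.40) passed adjusted over the list alone, and Fdps (1.40) and Sqle (1.20) did not. Tbx1 (1.80), Npnt (1.75), Wif1 (1.65) and Lhx2 (1.61) led the bulge list from high values in cKO mouse 1, with 520 reads of Tbx1 there against 38 in cKO mouse 2. Epidermal differentiation fell (18 of 22 negative, median -0.90, adjusted p = 7.3e-06, camera; adjusted p = 0.921 with an estimated correlation), with 3 of 22 lower adjusted over the list alone, Lce1a1 (-2.55), Hrnr (-1.88) and Flg2 (-2.16), and Tgm1 (-1.52) next. These genes were high in WT mouse 1, whose list level was 2.07 above the mean of the 4 libraries, and without it the median was 0.77 (adjusted p = 0.113, camera), against -2.37 without WT mouse 2. In the m6A list Alkbh5 alone passed adjusted over the list, and Igf2bp2 (-0.72), Ythdf2 (0.75) and Igf2bp3 (-0.65) did not (list adjusted p = 0.936, camera). Each of the 10 lists past the threshold lost its call in camera without 1 or more libraries.

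On recovered reads with TMM scaling, hair germ genes (median 0.87, adjusted p = 0.0047, camera), S phase (0.76, adjusted p = 1.74e-05), oxidative phosphorylation (0.87, adjusted p = 2.94e-09) and glycolysis (0.61, adjusted p = 0.0102) passed as higher. So did Hedgehog genes (0.38, adjusted p = 0.0405, camera), p53 targets (0.44, adjusted p = 0.0167), bulge genes (0.28, adjusted p = 0.0414) and cholesterol synthesis (0.15, adjusted p = 0.0157). Wnt genes did not pass on that scale (0.38, adjusted p = 0.0878, camera). Ribosomal protein genes passed there as higher (0.72, adjusted p = 0.0163, camera). Epidermal differentiation (-1.64, adjusted p = 8.36e-08, camera; 7 of 20 members lower), G2 and M phase genes (-0.22, adjusted p = 0.0258), immune cell genes (-0.48, adjusted p = 0.0248) and genes of muscle, fat, nerve and blood (-0.69, adjusted p = 0.0231) passed there as lower. On that scale too no list passed with an estimated correlation (adjusted p = 0.828 or more).

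Hair germ genes in SHERRY2 did not pass without cKO mouse 1 (median 0.68, adjusted p = 0.156, camera) and reached 1.63 without cKO mouse 2. Wnt genes did not pass without cKO mouse 1 (0.50, adjusted p = 0.258) or WT mouse 2 (0.24, adjusted p = 0.485), and their median was 0.03 without cKO mouse 2. S phase genes did not pass without cKO mouse 2 (0.38, adjusted p = 0.106, camera), with 0.63 without WT mouse 2. Oxidative phosphorylation genes did not pass without WT mouse 2 (0.49, adjusted p = 0.21) or cKO mouse 2 (0.60, adjusted p = 0.0702), and had 2.07 without cKO mouse 1. Glycolysis genes did not pass without WT mouse 2 (0.24, adjusted p = 0.835) or cKO mouse 2 (0.68, adjusted p = 0.0545), and Hedgehog genes without cKO mouse 1 (0.26, adjusted p = 0.594) or WT mouse 1 (0.68, adjusted p = 0.155). Bulge genes did not pass without cKO mouse 1 (0.27, adjusted p = 0.876) or WT mouse 2 (0.18, adjusted p = 0.21). Cholesterol genes did not pass without WT mouse 2 (0.08, adjusted p = 0.888), p53 targets without WT mouse 2 (0.11, adjusted p = 0.789) or cKO mouse 2 (0.29, adjusted p = 0.635), and epidermal genes also not without cKO mouse 1 (-0.12, adjusted p = 0.153).

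In hair germ stem cells measured by SMART-seq, Wnt and FGF response genes were lower as groups in the libraries labelled cKO, and no single gene passed. edgeR called 0 higher and 0 lower of 17547 genes, with 179 at an unadjusted p under 0.05, and DESeq2 called 0. Of 20 Wnt genes, 19 were negative, with a median of -0.53 (adjusted p = 8.45e-09, camera; adjusted p = 0.883 with an estimated correlation), below every one of the matched random lists. The S phase, G2 and M phase, hair matrix and immediate early lists lay below all of theirs too, so this placement does not single out Wnt. Wnt7a (log2 -2.94), Lef1 (-1.26), Wnt10b (-1.37) and Nkd1 (-0.97) led it, none passing adjusted over the list alone. Lef1, a nuclear partner of Wnt signalling that marks activated hair germ, had 25.3 ± 1.84 CPM in WT and 10.6 ± 2.44 in the libraries labelled cKO (n = 2 each). FGF and MAPK response genes had a median of -0.29 (11 of 16 negative, adjusted p = 0.00201, camera; adjusted p = 0.883 with an estimated correlation), with Etv4 (-1.22), Dusp6 (-0.54), Etv5 (-0.98) and Spry4 (-1.26) lowest in p. Of the 12 lists past the threshold in camera, only the Wnt and FGF lists kept their call in all 4 fits that left out 1 library, with Wnt medians from -1.14 (without labelled cKO mouse 1) to -0.21 (without labelled cKO mouse 2) and FGF medians from -0.63 (without labelled cKO mouse 1) to -0.34.

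Each of the other lists lost its call without 1 or more mice. Every fit without 1 mouse, also where the Wnt and FGF lists kept their call, left the sexes unequal between the genotypes. Lost calls and changed signs there cannot be assigned to genotype or sex alone. Hair germ genes (13 of 14 negative, median -0.37, adjusted p = 1.53e-05, camera), led by Lef1, Wnt10b, Msx2 (-0.88) and Runx1 (-0.46), did not pass without WT mouse 2 (-0.22, adjusted p = 0.301). S phase genes (21 of 22 negative, -0.51, adjusted p = 2.86e-07, camera; Dut -0.83, Cdc6 -1.03, Mcm4 -0.74, Cdt1 -0.88) did not pass without labelled cKO mouse 2 (0.02, adjusted p = 0.836) and had -1.59 without labelled cKO mouse 1. G2 and M phase genes (24 of 24 negative, -0.39, adjusted p = 1.53e-05, camera; Bub1 -0.79, Aurka -0.53, Birc5 -0.74, Hmmr -0.72) went higher without labelled cKO mouse 2 (median 0.44, adjusted p = 5.46e-06, camera) and did not pass without WT mouse 2 (0.34, adjusted p = 0.178). Cholesterol synthesis (16 of 19 negative, -0.34, adjusted p = 1.53e-05, camera; Insig1 -0.58, Sqle -0.43) did not pass without WT mouse 2 (-0.21, adjusted p = 0.114). Hair matrix and shaft genes (16 of 17 negative, -0.88, adjusted p = 0.0298, camera; Krt27 -1.89, Tchh -0.82) went higher without WT mouse 2 (median 1.06, adjusted p = 0.000122) and did not pass without labelled cKO mouse 2 (adjusted p = 0.31). Epidermal differentiation was higher (17 of 20 positive, 0.42, adjusted p = 0.00358, camera; Klk7 1.61, Sprr1a 0.88, Ivl 0.92, Grhl3 0.45), and lost its call without WT mouse 2 (adjusted p = 0.564) or labelled cKO mouse 1 (adjusted p = 0.918). Immune cell genes were higher (0.56, adjusted p = 0.0419, camera), a call lost without WT mouse 2 (adjusted p = 0.105) or labelled cKO mouse 2 (adjusted p = 0.881). TGF-beta targets (-0.36, adjusted p = 0.0366, camera) lost theirs without WT mouse 2 (adjusted p = 0.156) or either labelled cKO mouse (0.102 and 0.124), and ribosomal protein genes (-0.10, adjusted p = 0.0298) without WT mouse 1 (adjusted p = 0.772) or labelled cKO mouse 2 (0.942). Immediate early genes (-0.33, adjusted p = 0.0376, camera) went higher without WT mouse 1 (median 0.35, adjusted p = 1.09e-05) and did not pass without either labelled cKO mouse (0.159 and 0.124). All of these lists had an adjusted p of 0.883 with an estimated correlation. The p53 targets did not pass (7 of 14 positive, median 0.08, adjusted p = 0.216, camera), with Trp53inp1 at 0.57, Cdkn1a at 0.41, Pmaip1 at 0.42 and Mdm2 at 0.30, though they passed without labelled cKO mouse 1 (median 0.22, adjusted p = 0.0225).

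Of single genes, those of lowest p did not pass (adjusted p = 1 for each, edgeR). Higher were the calcium channel gene Cacna1e (log2 2.71), Atp10b (0.99), the glucocorticoid-induced repressor Zbtb16 (1.22), the pore-forming Gsdma (1.21) and the glutamine synthetase Glul (1.00). Zbtb16 had 177 ± 0.708 CPM in WT and 413 ± 120 in the libraries labelled cKO, and Glul 211 ± 33.8 and 422 ± 75.4. Lower were the histone genes H2ac23 (-3.14) and H4c9 (-1.23), the natriuretic peptide receptor Npr3 (-1.56), the protease Htra1 (-1.14) and Ace (-1.63). Atp10b, Glul, H2ac23, Npr3, Htra1 and Ace overlap other genes, so their reads are uncertain.

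**Figure D4:**
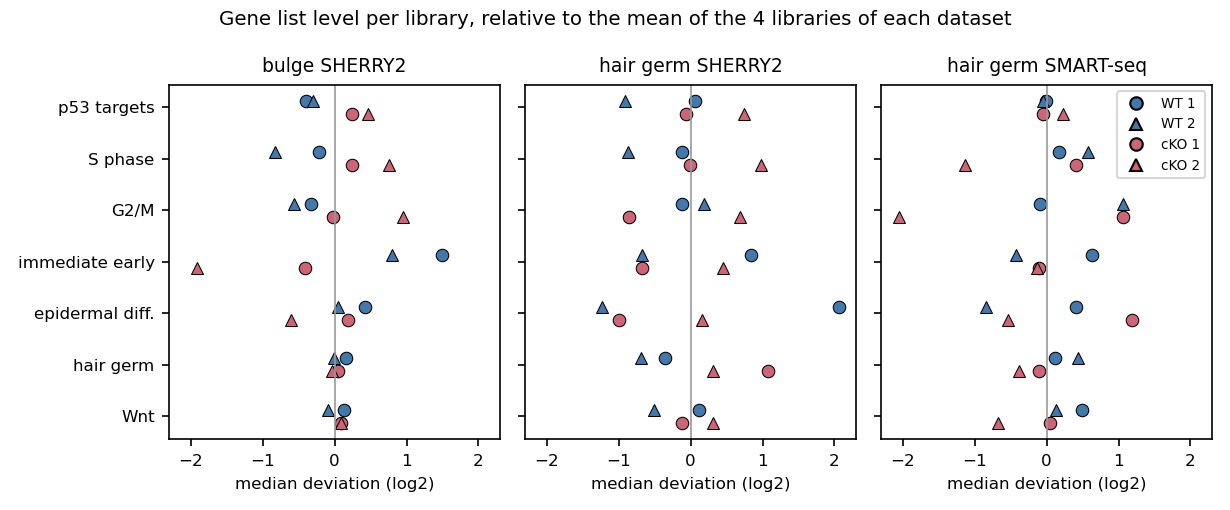
Median deviation of 7 gene lists per library, in log2 units from the mean of the 4 libraries of each dataset (WT blue, cKO red; mouse 1 circle, mouse 2 triangle). In the bulge the p53 targets of both cKO mice (0.236 and 0.458) lie above both WT mice (-0.403 and -0.307), while epidermal genes in hair germ SHERRY2 are set by WT mouse 1 (2.07).

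The hair germ protocols were set side by side to ask whether the genotype effect was shared. Across 16456 genes tested in both, the log2 fold changes of SHERRY2 and SMART-seq had a Pearson correlation of -0.118 and a Spearman correlation of -0.134 (genes are not independent replicates). Of 18 genes at an unadjusted p under 0.05 in both, against 9.06 for independent lists, 0 had the same direction. Etv4 and Wnt7a, which rose in the bulge (Etv4 by 2.09, adjusted p = 0.00843, edgeR) and had positive values in hair germ SHERRY2, had negative values in the SMART-seq libraries labelled cKO. No gene of 26257 differed between these effects in the joint edgeR fit, with 1012 at an unadjusted p under 0.05. Between the bulge and hair germ SHERRY2 the correlation was 0.069 over 14880 genes, and between the bulge and SMART-seq it was -0.0572 over 14054.

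Genes that changed in the bulge were followed into the hair germ. Of 222 genes higher in the bulge cKO, 186 were positive in hair germ SHERRY2, with a median of 0.55 against 0.21 to 0.37 for random lists of like expression and length (p = 1.72e-14, camera; p = 0.157 with an estimated correlation; p = 0.146, fry). Of 244 genes lower in the bulge cKO, 120 genes were negative, with a median of 0.02 against 0.59 to 0.76 for random lists (p = 0.794, camera; p = 0.97 with an estimated correlation). On recovered reads with TMM scaling, 150 of 220 were positive and 163 of 242 negative, with medians of 0.29 and -0.29. Random lists of like expression and length had medians of -0.08 to 0.08 and 0.31 to 0.47 on that scale. Camera with the preset correlation called the first set higher and the second set lower on these reads, unlike the second set in normalized counts. Neither set passed on them with an estimated correlation or in fry. Igfbp3 (-2.32 in limma), Arc (-2.31), Mcam (2.11), Ddit4l (1.99), Serpine2 (1.44) and Ccng1 kept their bulge direction there at an unadjusted p under 0.05. So did Ptp4a3 (3.62 in the bulge and 3.10 in hair germ SHERRY2), Igfbp2 (3.86 and 2.36) and Sulf2 (3.26 and 1.82), named after their values were seen, and none of them passed in limma on the hair germ. In the SMART-seq libraries labelled cKO, 67 of the 208 genes higher in the bulge were positive (median -0.15; p = 0.000969, camera, against the bulge direction; p = 0.339 with an estimated correlation). The 243 genes lower in the bulge had a median of -0.03 there (p = 0.413, camera; p = 0.828 with an estimated correlation).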

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

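The joint fits of 2 datasets, and the tests of swapped labels and of gene-level counting for Alkbh5 in SMART-seq, were chosen after the results were seen. What draws attention in this part is that the genotype effect on a gene differed between datasets when the difference itself was tested, in edgeR with Benjamini-Hochberg adjustment.

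Between hair germ SHERRY2 and the bulge, the effect differed for 31 of 26163 genes, and 1957 had an unadjusted p under 0.05. Of the 31 genes, 13 had the higher effect in the hair germ and 24 were among the genes called in the bulge. Several of the largest rises of the bulge cKO had smaller effects in the hair germ (differences of log2 fold changes, hair germ minus bulge). These were Gria3 (-9.52, adjusted p = 2.01e-06, edgeR), Celf5 (-5.90), Pde7b (-5.24), Slit1 (-5.04), Serpine2 (-5.04, adjusted p = 0.000362), Plod2 (-4.67), Col2a1 (-4.50) and Mcam (-3.87, adjusted p = 0.00245). The hair germ effects in this fit were -0.44 for Gria3, -0.75 for Celf5, 0.97 for Serpine2 and 1.77 for Mcam. Nr4a3, lower in the bulge cKO, had the higher effect in the hair germ (3.59, adjusted p = 0.0425, edgeR), and so did Alkbh5 itself (2.55, adjusted p = 0.042). Whether reads on otherwise silent genes in the hair germ SHERRY2 libraries lower such fold changes was not tested.

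Between hair germ SMART-seq and the bulge, the effect differed for 8 of 18849 genes, with 1276 at an unadjusted p under 0.05. All 8 genes were called in the bulge. Alkbh5 (difference 4.67, adjusted p = 0.0331, edgeR) and Glul (3.82, adjusted p = 0.0389) had the higher effect in the libraries labelled cKO of SMART-seq, and Mcam had the lower one (-5.64, adjusted p = 0.0389), with a SMART-seq effect of 0.02.

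Alkbh5 lay near its WT level in the SMART-seq libraries labelled cKO, at 83.57 and 104.9 CPM against 136 and 94.07 in WT. A swap of labels within the 4 libraries was argued against, because each library labelled WT also had at least 69.2% of the highest level. Gene-level counting of reads outside a deleted part was argued against for an allele shared by the datasets, because the SHERRY2 cKO groups kept 23% of the WT level or less. Whether the cells or mice lacked recombination cannot be told apart from other sources of this level. Genes called in the bulge gave a smaller fry p of 0.583 in these libraries, but also gave fry p of 0.146 and 0.959 in hair germ SHERRY2, where Alkbh5 fell, so the test leaves this open. An outside sample or another allele in this batch might also apply and was not tested.

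The p53 targets were higher in both bulge cKO mice than in both WT mice. Bias by gene length or expression level was argued against, since the list's median exceeded that of 100% of matched random lists. The male WT library was argued against as the source, since the median without it was 0.767. A difference in handling stress between mice cannot be told apart from a response to loss of Alkbh5. Between the cKO libraries the list differed by 0.0622, where 0.483 was predicted from the difference of -1.36 in immediate early genes, but 1 pair of mice gives no spread between mice. Either may apply.

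Reads on most listed genes in the shallow hair germ SHERRY2 libraries may come from genomic DNA or from whole gene bodies. Among 20657 genes with an ID at 0 reads in the bulge, reads rose with genomic span (Spearman rho 0.657) and more so with exonic size (0.767). Reads of genomic DNA counted in exons would follow exonic size, as reads of transcripts would, so these sources cannot be told apart by these values. More cell types among the sorted cells were argued against as the whole source. Over 508 receptor genes, which few cell types express, the median was 65.5% of the reads per kb of span of other such genes. Pooled, the receptor genes had 1.92 reads per kb, against a median of 4.98 for the others.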

How the results depend on the processing

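edgeR on recovered reads, with and without each library, was chosen after the data were seen, and the other alternatives were planned. Counts of genes moved by more than 1.5 times in these settings. In the bulge (476 genes with all libraries), DESeq2 gave 1187 and no low-count filter 1549, and leaving out 1 library gave 218 (without WT mouse 2) to 1601 (without cKO mouse 1). All 476 genes kept their sign in these fits, as was nearly given in advance by their non-overlapping groups. Of them, 472 were among the 1187 of DESeq2. That count moved under 2 changes, since DESeq2 was also run without the filterByExpr step, on 26954 genes against 15672. In hair germ SHERRY2 (3 genes), a pseudocount of 0.1, no filter on the mean and DESeq2 each gave 0, edgeR on recovered reads gave 63, and limma without 1 library gave 0 (without cKO mouse 1 or WT mouse 1) to 105 (without WT mouse 2). edgeR on recovered reads without 1 library gave 1 (without cKO mouse 1 or WT mouse 1), 16 (without cKO mouse 2) and 113 (without WT mouse 2). In SMART-seq (0 genes in edgeR, 179 at an unadjusted p under 0.05), no low-count filter gave 30, of which 9 were higher. The cause was not tested.

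With an estimated correlation, camera called 0 gene lists in each dataset, against 10 in the bulge, 10 in hair germ SHERRY2 and 12 in SMART-seq with the preset correlation. With so few residual degrees of freedom, the estimated form could call hardly any list. Leaving out 1 library in hair germ SHERRY2 gave 6 (without cKO mouse 1) to 11 lists in limma, and 6 lists without WT mouse 2 in edgeR on recovered reads.

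Directions reversed for genes that had not passed over all genes in limma or, for SMART-seq, in edgeR. Of them, Wif1 (adjusted p = 0.000886), Tbx1 (adjusted p = 0.024) and Flg2 (adjusted p = 0.000198) had passed in edgeR on recovered reads with all libraries. In limma on hair germ SHERRY2 without 1 library, log2 fold changes ran from -0.759 to 4.053 for Wif1, -0.209 to 3.428 for Lhx2 and -0.23 to 2.518 for Gli1 (lowest without cKO mouse 1). They ran from -0.2 (without WT mouse 1) to 2.673 for Cdkn1c, from -5.411 to 0.309 for Lce1a1 and from -4.319 to 0.007 for Flg2 (highest without WT mouse 1). In edgeR on recovered reads without cKO mouse 1, values were negative for Tbx1 (-0.327), Npnt (-0.128), Wif1 (-1.255), Lhx2 (-0.55) and Gli1 (-0.576), and without WT mouse 1 for Cdkn1c (-0.583).

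In SMART-seq without 1 library, Alkbh5 ran from -0.516 to 0.003 (without WT mouse 1). Lowest values without labelled cKO mouse 1 and highest values without another library were -2.2 and 0.212 for Bub1 and -3.036 and 0.086 for Birc5 (above 0 without WT mouse 2, at 0.009 for Birc5). They were -1.701 and 0.087 for Aurka and -3.394 and 0.148 for Hmmr (above 0 without labelled cKO mouse 2). Tchh ran from -1.427 to 0.26 (without WT mouse 2), Mdm2 from -0.031 (without labelled cKO mouse 2) to 0.589, Ivl from -0.504 to 1.614 and Grhl3 from -0.048 to 0.822 (lowest without labelled cKO mouse 1).

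With the mouse number as a replicate block, the bulge gave 506 genes, of which 409 were among the 476, and 10 lists, and SMART-seq gave 0 genes and 15 lists. The lists gained in SMART-seq were bulge stem cell genes (adjusted p = 0.0236, camera), the Hedgehog pathway (adjusted p = 0.0171) and Hippo targets (adjusted p = 0.0473), all lower. The deviations of mice with the same number had a correlation of -0.072 in the bulge and 0.23 in SMART-seq, where the numbers also differ in sex. In SMART-seq the fit without a block thus left the difference between the sexes in its spread. With the block, 343 genes there had an unadjusted p under 0.05, against 179 without it. With 2 mice per group and no label that ties a number to a litter or day, the numbers were not taken as pairs. No paired analysis was made for hair germ SHERRY2, because its mouse numbers rest on column names alone.

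Of single genes followed across the settings, each taken in each setting, 508 values in the bulge stayed on the same side of the threshold, 57 went past it and 43 no longer passed, with none reversed. In hair germ SHERRY2, 444 stayed, 36 went past, 17 no longer passed and 12 reversed. In SMART-seq, 313 stayed, 5 went past and 10 reversed. RLE size factors and a log2 fold change over 1 moved no count of genes by more than 1.5 times. Library-size scaling of Alkbh5 (-4.77, -2.34 and -0.26) and genes above the median in both hair germ protocols (correlation -0.2) moved those results by less than the spread between mice or, for the correlation, by less than 0.1. A fit without 1 library assumes that the lone sample left in its group varies like the others. In SMART-seq such a fit also leaves the sexes unequal between the genotypes. Alternatives planned for the m6A libraries, for hair germ against bulge and for both hair germ protocols in 1 fit were not run, nor was a pseudocount for read counts, RLE scaling of normalized values, or a fit of fewer groups, since each fit held only the groups compared.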

Other observations

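The lists of clock genes and glucocorticoid-induced genes were written after the first results were seen, and the test of the glucocorticoid list after its values were seen. Gene Ontology terms were an addition as well. In the bulge cKO libraries, clock genes changed in opposite directions. Per2 rose from 11.9 to 46.7 CPM (log2 1.96, adjusted p = 0.0417, edgeR) and Per3 from 35.4 to 77.3 (1.13, adjusted p = 0.019), while Arntl, which drives their transcription, fell from 44.3 to 24.8 (-0.84, adjusted p = 0.0465). Of 16 clock genes, 3 passed over all genes. Per1 (-0.37) did not pass.

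Glucocorticoid-induced genes were lower in the bulge cKO libraries. All 15 were negative with a median of -1.73, and 10 passed over all genes in edgeR. Glul, which makes glutamine, fell from 586 to 82.6 CPM (adjusted p = 0.00277, edgeR), Txnip, which restrains glucose uptake, from 2800 to 606 (adjusted p = 0.0041), Mt1 from 526 to 115 (adjusted p = 0.0161) and Zbtb16 from 121 to 49 (adjusted p = 0.0375). Among terms, interstrand cross-link repair was higher (adjusted p = 8.75e-05, camera), and cytoplasmic translation (adjusted p = 1.75e-15), antibacterial humoral response (adjusted p = 0.000506) and antigen presentation by MHC class II (adjusted p = 0.0017) were lower. Each of these terms had an adjusted p of 0.999 with an estimated correlation.

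A different time of day at sampling may underlie the clock genes, but it cannot be told apart from the wide change of the bulge cKO libraries. The smallest fry p for change in either direction over the 3 comparisons was 0.00508, in the bulge, with 0.444 in hair germ SHERRY2 and 0.774 in SMART-seq. In the bulge, 8 of 34 gene lists had as low a value, so it does not single out the clock. The list median was 0.32 there, above random lists of like expression and length (-0.18 to 0.20). It was -0.475 in the SMART-seq libraries labelled cKO, below such lists (-0.16 to 0.12), with 12 of 16 genes negative. Per2 (-1.11), Per3 (-1.24) and Arntl (0.42) had signs there opposite to the bulge, without passing. In hair germ SHERRY2 the median was 0.32, inside its random lists (0.1 to 0.67). Genes of 1 list are not independent replicates, so sampling time stays open. Sampling times are not given in the sources used here.

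A difference in glucocorticoid exposure between mice, by stress or by hour, might underlie the glucocorticoid-induced genes, and it cannot be told apart from an effect of genotype. In the SMART-seq libraries labelled cKO, 11 of 15 were positive with a median of 0.18 and a fry p of 0.0501, which misses the threshold set for a change opposite to the bulge. Camera with the preset correlation gave a p of 9.44e-06 there, and the median exceeded that of 99.8% of matched random lists. In hair germ SHERRY2, 8 of 15 were positive with a median of 0.03, below random lists (0.33 to 0.94), and a fry p of 0.906. Tsc22d3 (1.46), Zbtb16 (1.22) and Glul (1.00) were highest in those SMART-seq libraries without passing (adjusted p = 1, edgeR). Exposure is confounded with genotype at 2 mice per group, which keeps this open.

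Whether hair germ cells share the bulge changes stays open as well. In hair germ SHERRY2 the larger fry p of the genes higher and the genes lower in the bulge cKO was 0.959. fry tests against a change of 0, while random lists like the lower genes had medians of 0.59 to 0.76 on that scale. That p therefore cannot decide, with 2 mice per group and this background. Beside random lists, the higher genes lay above (0.55 against 0.21 to 0.37) and the lower genes below (0.02), but genes are not independent replicates. Igfbp3, Arc, Ptp4a3 and Sulf2, which passed in the bulge, might be shared, as single genes chosen after their values were seen.

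Higher p53 targets beside higher S phase and G2 and M phase genes may reflect replication stress in bulge cells that enter the cycle, as a hypothesis from these libraries alone. Without the male WT mouse the lists had similar medians, 0.767 for p53 targets, 0.78 for S phase and 0.88 for G2 and M phase, so that fit did not separate them. Without cKO mouse 1 or cKO mouse 2, the medians were 1.45 and 0.40 for G2 and M phase and 0.86 and 0.56 for p53 targets, so p53 targets differed less between the cKO mice. Staining for DNA damage marks in bulge cells of further cKO mice, matched for sex and hour, would test it.

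Loss of Alkbh5 could act on transcripts that carry m6A. This was not tested, because m6A libraries were not analysed here. In the RNA libraries, other m6A enzymes and readers did not pass in the bulge, and Serpine2, Mcam and Gria3 would be first candidates for a test of m6A and of RNA half-life. All 3 were among the 19 named bulge genes, of which none but Ccrl2 (without WT mouse 1) and Pde7b (without WT mouse 2) lost its call in a fit without 1 library. Without WT mouse 2, the fit with fewest calls had 218.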
